A study of Homo sapiens with 8 samples.

How the data were processed

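RNA sequencing libraries of the cell line CRL-4003 were grouped by the labels into undifferentiated cells (3 libraries), cells treated with cAMP and MPA for 3 days (3) and for 8 days (2). Per the labels, cells were detached with trypsin before RNA was isolated with a column kit. The deposited table gives raw read counts per Ensembl gene, which by their heading come from HTSeq, and transcripts per 1000000 (TPM). The submission names CASAVA 1.4, TopHat2 2.0.5, HTSeq and GRCh37 without further detail. The annotation release, the strand setting and the treatment of reads that map to several places are not stated in the sources used. The deposited TPM values, written with decimal commas, were read and tested against the counts: over 8623 genes with at least 200 counts they equal the count divided by a fixed length per gene and scaled to the same sum in every library, so they are not an independent measurement. No coordinates were used, since the annotation available here is of another genome build. Symbols and Ensembl identifiers are those of the table.

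Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 3 groups, which left 15148 of 60379, and libraries were scaled by TMM. A quasi-likelihood model with robust estimation was fitted to all 8 libraries with 3 group means, so that day 8, with 2 libraries, shared the spread of the others. The 3 contrasts were tested with the quasi-likelihood F test, and genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested are called changed. A second count requires an absolute log2 fold change of at least 1. Tests are two-sided. The SE of a log2 fold change is its size divided by the square root of F. CPM values are counts per 1000000 of the TMM-scaled library size, and principal components used log2 CPM with a prior count of 2. Where all libraries of a group had no count, the fold is a lower bound computed against 3 counts in each library of that group. Where a group had 1 to 3 counts in all, the ratio of pooled counts is given with an exact 95% binomial interval.

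The 29 gene lists hold 648 entries for 628 distinct genes. Of these, 645 were found in the table, 1 by another symbol, and CD24, SC4MOL and PKM2 were not found. Some genes stand in several lists. For 4 list genes (LAMA4, OCLN, MMP12 and NCAM1) a second entry of the same symbol also had counts, and the values of these genes are uncertain. The lists are decidual markers, progestin and glucocorticoid targets, cAMP and CREB targets, steroid receptors and cofactors, uterine stromal transcription factors, mitosis, DNA replication, CDK inhibitors, interstitial matrix, basement membrane, matrix proteases and inhibitors, contractile and SRF target genes, and WNT signalling. They further include insulin and IGF signalling, TGF-beta and BMP signalling, interferon-stimulated genes, inflammatory cytokines and chemokines, complement, cholesterol synthesis, steroid and retinoid metabolism, unfolded protein response, oxidative stress defence, glucose uptake and glycolysis, angiogenic factors and circadian clock. The last 4 hold markers of epithelial cells, endothelial cells, leukocytes, and pericytes and smooth muscle. Members called higher and lower were counted with p adjusted over all genes and over the list alone. Each list was compared with the other genes by camera (limma 3.58.1) with a preset correlation of 0.01, which is the list test of the text, and again with an estimated correlation. The fry test asks whether the genes of a list move, on balance, in 1 direction and does not compare the list with other genes. List p values were adjusted over the 29 lists.

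Courses over time were defined from the 3 calls. Held means called at both time points in 1 direction with no call between them, and continued means called at day 3 and again in that direction from day 3 to day 8. Transient, partly returned and reversed genes have a day 3 call and an opposite call from day 3 to day 8, with respectively no call, a call in the day 3 direction and an opposite call at day 8 against undifferentiated cells. Late genes have no day 3 call and calls in 1 direction for both day 8 contrasts. Shared calls were compared with independent lists and with 20 simulated data sets each for no difference between groups and for day 8 equal to day 3.

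Genes named in the text follow a rule. For each comparison they are the 8 largest rises and 8 largest falls with a mean count of at least 100 in the higher group and no overlap between libraries, and the 4 members of each list with the largest change and a mean count of at least 20 in the higher group. Also named are 5 genes of each course over time and PRL, IGFBP1, FOXO1, PGR, HAND2, HOXA10, HOXA11, CEBPB, WNT4, BMP2, ZBTB16, FKBP5, MKI67, ACTA2 and COL1A1. Other genes are marked where they are named. The comparisons, tests, lists, this rule, the alternatives and the definition of opposite effects were all choices made before the data were examined.

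The tests were tried on simulated data, drawn with the levels, library sizes and spread estimated from these libraries, in which 200 genes were changed by known folds. Alternatives to the main choices were scaling by the median of ratios and by upper quartiles, no filter and a stricter filter (at least 1 CPM in every library of a group and a mean count of 20), the DESeq2 1.42.0 Wald test, limma-voom, a fit to only the groups compared and the replicate number as a block. Leaving out each library in turn, and limma-trend on log2(TPM + 1) and log2(TPM + 0.1) for genes with at least 1 TPM in 2 libraries, and on log2(TPM + 1) without a filter, were also run. Tables were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No library was left out. Total counts ranged from 25446911 to 42294133, and intervals and limits cover counting error only.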

Results

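RNA was sequenced from CRL-4003, an immortalized line of human endometrial stromal fibroblasts, before and during decidualization. Decidualization is the change of these fibroblasts into secretory decidual cells, which progesterone drives in the uterus. In culture it was induced with cyclic AMP (cAMP, an intracellular second messenger) and medroxyprogesterone acetate (MPA, a synthetic progestin). The 8 libraries comprised 3 of undifferentiated cells, 3 of cells after 3 days with cAMP and MPA (day 3) and 2 of cells after 8 days (day 8). Total counts were 42294133, 40763631 and 38900125 in the undifferentiated libraries, 25500263, 25446911 and 37827636 at day 3, and 32192416 and 32917391 at day 8. The labels do not say whether the replicates were separate cultures, and they give no time in culture for the undifferentiated cells.

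Of 60379 genes in the table, 32675 had no count in any library and 15148 passed the filter on low counts. Values per group are means ± SD of normalized counts per 1000000 (CPM) over 3 undifferentiated, 3 day 3 and 2 day 8 libraries, with log2 fold changes and their standard errors (SE) from the model fitted to all 8. A count of 0 in a library allowed a level of up to 0.0745 to 0.111 CPM, the value of 3 counts. Such limits, and the intervals given for ratios with few counts, cover counting error only. No genome coordinates are given, because the deposited counts were made on GRCh37 and only an annotation of GRCh38 was at hand. For the genes named here as higher or lower by the test, the libraries of the groups compared did not overlap, with the exceptions of ITGA11 and CD68 at day 3. With 3 libraries against 3, chance alone separates 10% of genes in this way, and with the 2 day 8 libraries against 3 the share is larger. The largest rises and falls were also chosen for this lack of overlap, so for them it is no added support.

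The first principal component of log2 CPM held 73.7% of the variance and separated undifferentiated from treated libraries, and the second, with 19.7%, separated day 3 from day 8. The third component held 2.40% and set undifferentiated replicate 3, at −28.9, apart from replicates 1 and 2, at 13.4 and 16.5. It also spread day 3 replicates 1 to 3, at −1.60, −16.5 and 18.4. The 10 most abundant genes took 9.90% ± 0.735 of all counts in undifferentiated cells, 6.31% ± 0.0553 at day 3 and 6.32% ± 0.138 at day 8. Mitochondrial protein-coding genes took 0.668% ± 0.161, 1.39% ± 0.379 and 1.51% ± 0.0369 of the counts, so this share moved with treatment. The biological coefficient of variation across replicates was 10.1%.

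**Figure D1:**
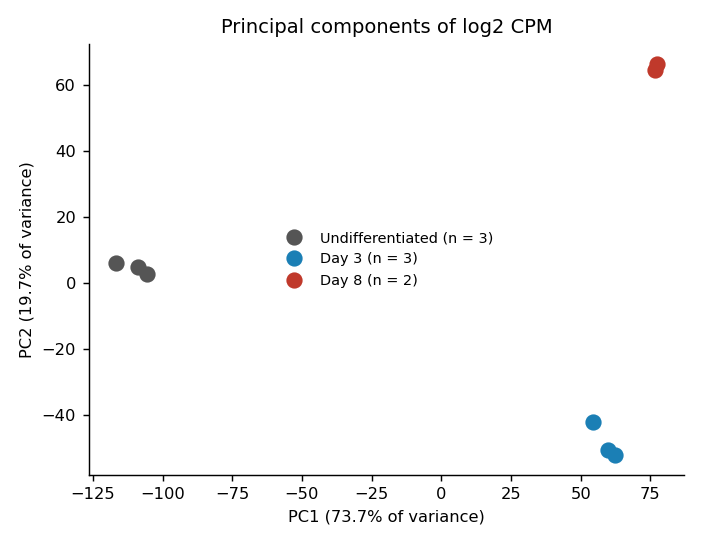
Libraries on the first and second principal components of log2 CPM, with the share of the variance on each axis. The first component (73.7%) parts the 3 undifferentiated libraries from the 5 treated ones, and the second (19.7%) parts day 3 from day 8.

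The comparison of day 3 with undifferentiated cells asked which genes respond early to the decidualizing treatment. IGFBP1 (ENSG00000146678), which encodes a secreted insulin-like growth factor binding protein used to mark decidual cells, rose from 0.131 ± 0.0738 to 238 ± 37.0 CPM, a log2 fold change of 10.78 (SE 0.25, adjusted p = 1.61e-10). PRL (ENSG00000172179), encoding the hormone prolactin, another such marker, had no count in undifferentiated cells and reached 4.03 ± 0.65 CPM, at least 50.6-fold higher. The transcription factor gene FOXO1 (ENSG00000150907) rose from 1.63 ± 0.238 to 230.2 ± 17.9 CPM, a log2 fold change of 7.14 (SE 0.12, adjusted p = 5.05e-11). MKI67 (ENSG00000148773), a marker of dividing cells, fell 366-fold, from 418 ± 73.7 to 1.15 ± 0.254 CPM (SE of log2 0.18, adjusted p = 1.3e-10).

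Across all genes tested, 10958 (72.3%) changed at day 3, with 5459 higher and 5499 lower. A change of at least 2-fold was seen in 5208, of which 2842 were higher and 2366 lower, and 8-fold or more in 579 higher and 548 lower genes. A further 318 genes had an unadjusted p under 0.05 and were not called. The 2-fold count fell to 3300 with the deposited transcripts per 1000000 (TPM) on a log2(TPM + 1) scale, on which low values shrink, and to 3294 without a filter on low values. On those scales the share of changed genes that were higher was 61.3% and 60.8%, against 49.8% with the counts and 54.7% with upper-quartile scaling of the counts, and the median gene moved by 0.18 on the former. The TPM settings also changed the scaling, the test and the genes kept. Among the genes with the largest rises, LINC00473, a long non-coding RNA gene, went from no count to 43.7 ± 4.24 CPM, at least 549-fold higher. Counting was not stated to respect strand, which limits assignment of reads for such genes where others overlap. ADH1B (alcohol dehydrogenase) and RORB (a nuclear receptor) also started from no count and were at least 232-fold and 146-fold higher. Outside the 8 largest rises by fitted fold change, CGA (ENSG00000135346), encoding the alpha subunit of the glycoprotein hormones, rose from 0.185 ± 0.0152 to 277 ± 40.2 CPM. Fitted fold changes of genes with no undifferentiated count, such as RORB, rest on a group without counts, so their rank against CGA is uncertain. DIRAS2, a small GTPase gene with 0.0094 ± 0.0163 CPM in undifferentiated cells, had 27.1 ± 1.68 CPM at day 3, a ratio of 3040 with a 95% interval of 545 to 120120. Among the largest falls were those of FAM111B to 0.0857 ± 0.0554 CPM (log2 fold change −9.21) and of MCM10 to 0.106 ± 0.162 CPM (log2 fold change −8.90).

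Of the 29 gene lists fixed in advance, 14 passed the list test at day 3, 10 of them upward. When the correlation between members was estimated from the data, 1 still passed, the targets of cAMP and its transcription factor CREB (adjusted p = 0.0487). In this list 17 of 19 tested members rose, none fell, and PDE3B and AREG, the latter named after its value was seen, were not past the threshold. Its median log2 fold change was 2.70 (adjusted p = 9.95e-08 with the preset correlation). Besides CGA, its members PDE3A, PDE7B and SST stood out: PDE3A rose by a log2 fold change of 7.80 (SE 0.25) and PDE7B by 5.79 (SE 0.11), while SST (somatostatin) reached 2.00 ± 0.791 CPM, a ratio of 214 with a 95% interval of 37.9 to 8502.

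Among 18 tested decidual markers, 17 rose at day 3, with a median log2 fold change of 4.91, or 3.65 with the 4 members that had no undifferentiated count at their lower bound (adjusted p = 5.53e-08, and adjusted p = 0.104 with an estimated correlation). DKK1, named after its value was seen, fell by 0.23 on the log2 scale. WNT4 (ENSG00000162552), a signalling ligand gene, was at least 130.2-fold higher at 10.4 ± 0.821 CPM, and LEFTY2 at least 27.2-fold higher. The transcription factor genes HAND2 (ENSG00000164107) and CEBPB (ENSG00000172216) rose 7.33-fold to 264 ± 5.75 CPM and 3.65-fold to 146 ± 18.8 CPM. BMP2 (ENSG00000125845) rose 2.69-fold, from 2.5 ± 0.191 to 6.75 ± 0.365 CPM. ZBTB16, a progestin-responsive transcription factor gene, reached 12.6 ± 0.104 CPM from 0.0094 ± 0.0163, a ratio of 1424 with a 95% interval of 255 to 56303.

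Genes that progestins and glucocorticoids induce rose in 15 of 16 cases, with a median log2 fold change of 3.50 (adjusted p = 3.45e-07, and adjusted p = 0.0624 with an estimated correlation). STC1 fell by 1.66 on the log2 scale. CDKN1C, encoding a cyclin-dependent kinase inhibitor, rose 151-fold to 25.9 ± 1.43 CPM, MAOA 93.9-fold and KLF9 39.7-fold. FKBP5 rose from 6.91 ± 0.443 to 44.9 ± 1.24 CPM. The progesterone receptor gene PGR (ENSG00000082175) rose from 30.2 ± 3.83 to 87.3 ± 1.95 CPM (log2 fold change 1.53, SE 0.09). Over the steroid receptors and their cofactors, 8 rose, 5 fell and 1 was not past the threshold, with a median of 0.25 (adjusted p = 0.573). Of 24 uterine stromal transcription factors, 16 rose, 4 were not past the threshold and 4 fell, which were HOXA9, HOXD8, GATA2 and NR2F2, named after their values were seen. The median of that list was 1.05 (adjusted p = 0.000446, and adjusted p = 0.108 with an estimated correlation). CEBPD rose 68.2-fold to 282 ± 37.2 CPM, MEIS1 5.83-fold, HOXA11 3.27-fold and HOXA10 2.05-fold.

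All 28 mitosis genes and all 30 DNA replication genes were lower at day 3, with no undifferentiated library labelled as kept in culture as long. The median log2 fold change was −5.81 for mitosis (adjusted p = 3.23e-16, and adjusted p = 0.104 with an estimated correlation) and −3.65 for replication (adjusted p = 2.14e-15, and adjusted p = 0.0589 with an estimated correlation). CDC20 fell 177-fold to 1.19 ± 0.354 CPM, DLGAP5 225-fold, BUB1B 187-fold and CCNE2 142-fold. Of 8 genes for inhibitors of cyclin-dependent kinases, 4 rose and 4 fell (adjusted p = 0.971). CDKN1A rose 3.35-fold to 938 ± 88.7 CPM and CDKN2B 2.71-fold, while CDKN2C fell 3.18-fold and CDKN3 29.3-fold.

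Contractile genes and targets of the serum response factor (SRF) fell in 18 of 20 cases, with a median log2 fold change of −1.14 (adjusted p = 0.000139, and adjusted p = 0.224 with an estimated correlation). ACTA2 (smooth muscle actin) fell from 586 ± 87.2 to 189.5 ± 10.6 CPM and TPM1 from 3024 ± 248 to 443 ± 19.2 CPM. LMOD1 and CALD1 rose, by 2.17 and 0.40 on the log2 scale, CALD1 being named after its value was seen. Interstitial matrix genes moved both ways, with 10 higher, 13 lower and 4 not past the threshold (adjusted p = 0.714). COL14A1 rose 249-fold to 20.8 ± 3.81 CPM and DCN (decorin) from 32.8 ± 2.07 to 780.2 ± 38.1 CPM. TNC (tenascin C) fell 22.8-fold, VCAN (versican) 12.4-fold, and COL1A1 from 11983 ± 2850 to 5161 ± 242 CPM.

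Insulin and insulin-like growth factor (IGF) genes rose in 15 of 18 cases, with a median log2 fold change of 1.81 (adjusted p = 0.00019, and adjusted p = 0.0728 with an estimated correlation). IGFBP3, IGFBP5 and PAPPA2 fell, of which IGFBP3 and PAPPA2 were named after their values were seen. PAPPA rose 67.5-fold to 813 ± 51.6 CPM and IGF2 24-fold to 183 ± 6.72 CPM. Complement genes rose in 12 of 13 cases, with a median of 2.70 (adjusted p = 0.000248, and adjusted p = 0.0624 with an estimated correlation). Of the genes entered in this list, C1QTNF1 rose 28.1-fold and C1R 15.8-fold, while C5, named after its value was seen, fell by 1.44 on the log2 scale. Entry in the list does not by itself make a gene, such as C1QTNF1, a complement component. Cholesterol synthesis genes rose in 21 of 23 cases and fell in none, with a median fold change of 2.64 (adjusted p = 4.52e-08, and adjusted p = 0.104 with an estimated correlation). PMVK and STARD4, named after their values were seen, were not past the threshold. TM7SF2 rose 17.1-fold and DHCR7 6.64-fold.

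Interferon-stimulated genes rose in 22 of 28 cases at day 3, with a median log2 fold change of 1.20 (adjusted p = 0.00144, and adjusted p = 0.443 with an estimated correlation). IFI44L rose from 0.0348 ± 0.0131 to 21.9 ± 1.31 CPM, ISG20 17.4-fold and OAS2 6.49-fold. Against these, 5 members fell: IFIT1 by 1.31, IFIT2 by 0.88, IFIT3 by 0.65, IFIT5 by 0.49 and OAS3 by 1.16 on the log2 scale. Of these, IFIT3 and IFIT5 were named after their values were seen, as was HERC5, which was not past the threshold. Steroid and retinoid metabolism genes rose in 10 of 16 cases, with a median of 1.59 (adjusted p = 0.0126, and adjusted p = 0.104 with an estimated correlation), and fell in 3. The latter were SRD5A1, CRABP2 and STRA6, named after their values were seen. ALDH1A1 was at least 48.5-fold higher, and HSD11B1 rose 21.5-fold. Genes of the defence against oxidative stress rose in 17 of 26 cases, with a median of 0.86 (adjusted p = 0.00187, and adjusted p = 0.0728 with an estimated correlation). Of the genes entered in this list, TXNIP rose 9.77-fold and SESN1 7.7-fold. Membership does not tell whether a gene adds to the defence or restrains it. Of the 4 that fell, MT2A fell 4.22-fold, and PRDX1, PRDX6 and MT1E were named after their values were seen. Genes for glucose uptake and glycolysis fell in 16 of 23 cases, with a median of −0.61 (adjusted p = 0.0106, and adjusted p = 0.58 with an estimated correlation). PFKP fell 5.65-fold and ENO1 4.03-fold. The 5 that rose included ALDOC, 11.6-fold, and SLC2A12, 7.87-fold, the others being SLC2A8, PFKM and PFKFB4, named after their values were seen.

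The other lists were not past the list test at day 3. Adjusted over the list alone, 1 more transcription factor gene and 1 more basement membrane gene were higher, and 1 more interstitial matrix gene and 1 more glycolysis gene lower, and the counts of the other 25 lists were the same. The sign of the median differed from that of the mean for the inhibitors of cyclin-dependent kinases (−0.37 and 0.22), interstitial matrix (−0.35 and 0.11), leukocyte markers (0.51 and −0.25) and pericyte markers (0.07 and −0.60), and the list test followed the mean in these with the exception of the matrix list. In a self-test with known changes in 200 genes, the test found 68.7% of 2-fold and 89.4% of 4-fold changes at day 3, with 12 false calls. Far fewer genes changed there than the 10958 called in the data. These figures therefore cannot be taken as the share found or the false calls of the comparison itself.

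**Figure D2:**
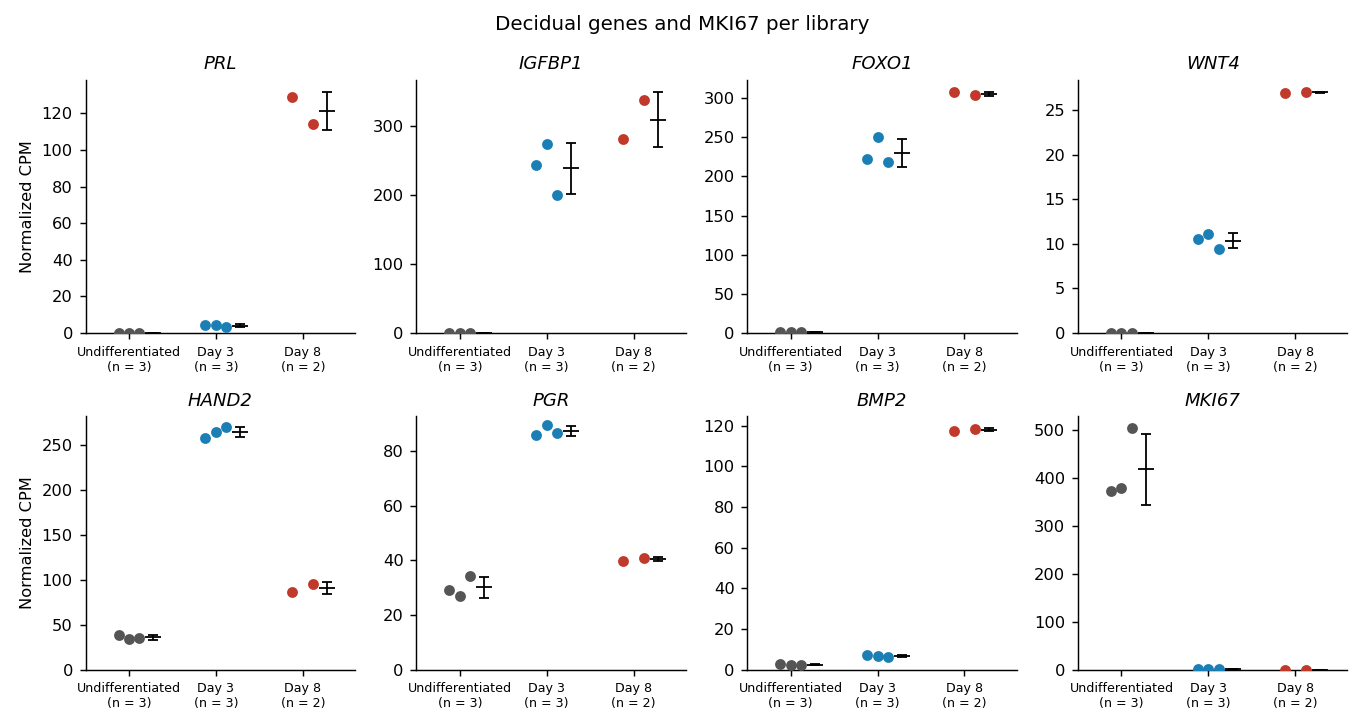
Normalized CPM per library of PRL, IGFBP1, FOXO1, WNT4, HAND2, PGR, BMP2 and MKI67 in undifferentiated, day 3 and day 8 cells, with the mean and SD of each group. HAND2 and PGR are highest at day 3 (264 and 87.3 CPM), PRL and BMP2 at day 8 (121 and 118 CPM).

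The comparison of day 8 with undifferentiated cells asked the same of cells treated for longer. PRL reached 121 ± 10.4 CPM from no count, at least 1526-fold higher. IGFBP1 was at 309 ± 40.2 CPM, a log2 fold change of 11.15 (SE 0.25, adjusted p = 1.6e-10). IGF2 (ENSG00000167244) rose 349-fold, from 7.64 ± 1.03 to 2664 ± 36.3 CPM (SE of log2 0.12, adjusted p = 3.11e-11). MKI67 fell 1089-fold to 0.381 ± 0.0271 CPM (SE of log2 0.25, adjusted p = 2.9e-10).

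At day 8, 10508 genes (69.4%) changed, 5246 higher and 5262 lower, and 5293 changed by at least 2-fold, 2786 higher and 2507 lower. Changes of 8-fold or more comprised 679 higher and 588 lower genes. A further 358 genes had an unadjusted p under 0.05 and were not called. On the log2(TPM + 1) scale the 2-fold count was 3428, and 3415 without a filter, with 57.3% and 58.5% of changed genes higher against 49.9% with the counts. Beside PRL, the largest rises from no count were those of EDNRB (endothelin receptor type B), at least 2257-fold to 179.6 ± 21.1 CPM, HSD17B2, which encodes an enzyme that inactivates estradiol, at least 1181-fold to 94 ± 1.91 CPM, and MMP7 (matrilysin), at least 707-fold to 56.2 ± 7.42 CPM. DIRAS2 reached 83.7 ± 0.227 CPM, a ratio of 9489 with a 95% interval of 1702 to 374850. GRIA4, a glutamate receptor gene, rose 1842-fold to 543 ± 16.7 CPM. The largest falls included NGF (nerve growth factor), from 8.1 ± 0.927 CPM to no count, at least 88.7-fold lower, and KIF20A, 704-fold to 0.258 ± 0.104 CPM.

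At day 8, 16 of the 29 lists passed the list test, 12 upward, and with an estimated correlation 1 passed, again the targets of cAMP and CREB (adjusted p = 0.0248). All 19 of its members were higher than in undifferentiated cells, with a median log2 fold change of 3.58 (adjusted p = 6.08e-10). PDE3A rose 644-fold and RGS2 186-fold, to 25.1 ± 0.451 and 143 ± 12.1 CPM. Decidual markers rose in 14 of 18 cases, with a median of 6.55, or 5.20 with the 4 members that had no undifferentiated count at their bound (adjusted p = 2.24e-05, and adjusted p = 0.15 with an estimated correlation). TIMP3 fell by 2.26 on the log2 scale, and DKK1 by 1.91, while IL15 and CRYAB were not past the threshold. The last 3 were named after their values were seen. BMP2 rose 47.2-fold to 118 ± 0.649 CPM, FOXO1 187-fold to 305 ± 2.79 CPM, HAND2 2.51-fold to 90.7 ± 6.38 CPM and CEBPB 3.68-fold to 148 ± 4.83 CPM. WNT4 was at least 339-fold higher at 27 ± 0.059 CPM. ZBTB16 was at 3.15 ± 0.277 CPM, a ratio of 357 with a 95% interval of 63.4 to 14173.

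Targets of progestins and glucocorticoids rose in 14 of 16 cases at day 8, with a median log2 fold change of 3.36 (adjusted p = 1.32e-05, and adjusted p = 0.0782 with an estimated correlation). SGK1 and NFKBIA, named after their values were seen, each fell by 0.59 on the log2 scale. CDKN1C rose 316-fold, MAOA 126-fold and FKBP5 2.89-fold, and MAOB reached 17.3 ± 0.0584 CPM, a ratio of 1965 with a 95% interval of 352 to 77681. PGR was 1.34-fold higher at 40.4 ± 0.789 CPM (log2 fold change 0.42, SE 0.10, adjusted p = 0.00385). Transcription factors rose in 16 of 24 cases and fell in 6, with a median of 0.81 (adjusted p = 0.0106, and adjusted p = 0.198 with an estimated correlation). NR2F1 rose 8.29-fold, CEBPD 15.4-fold and HOXA11 1.78-fold, and HOXA10 was not past the threshold at 50.3 ± 1.18 CPM (log2 fold change 0.03, SE 0.08, adjusted p = 0.746).

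All 28 mitosis and all 30 replication genes were lower at day 8, with medians of −6.73 (adjusted p = 1.18e-17, and adjusted p = 0.0941 with an estimated correlation) and −4.18 (adjusted p = 2.67e-16, and adjusted p = 0.052 with an estimated correlation). CDC20 fell 677-fold, and E2F2 fell from 6.97 ± 0.0839 CPM to no count, at least 76.3-fold. Contractile genes and SRF targets fell in 15 of 20 cases, with a median of −1.08 (adjusted p = 0.000375, and adjusted p = 0.203 with an estimated correlation). ACTA2 fell 6.13-fold to 95.7 ± 8.01 CPM, CNN1 6.71-fold and TAGLN 5.16-fold. The 3 that rose were CTGF, by 1.46 on the log2 scale, LMOD1, by 0.81, and ANKRD1, by 0.60. ANKRD1 was not past the threshold with no filter on low counts (adjusted p = 0.185). It was also not past it without undifferentiated replicate 1 (0.0572) or 2 (0.058) or day 8 replicate 1 (0.0814) or 2 (0.131), with a range of 0.000478 to 0.185 over its 19 alternatives. Pericyte and smooth muscle markers fell in 6 of 8 cases, with a median of −1.15 (adjusted p = 0.0225, and adjusted p = 0.126 with an estimated correlation). CSPG4 fell 15.9-fold, DES fell from 1.71 ± 0.441 to 0.0154 ± 0.0217 CPM, and NOTCH3 rose 3.31-fold.

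Complement genes rose in 12 of 13 cases at day 8, with a median log2 fold change of 3.82 (adjusted p = 5.97e-05, and adjusted p = 0.0551 with an estimated correlation), while C5 fell by 2.99 on the log2 scale. CLU (clusterin) rose 24.9-fold to 2243 ± 108 CPM, and A2M, a protease inhibitor gene outside that list, was at least 129-fold higher at 10.3 ± 1.48 CPM. Insulin and IGF genes rose in 15 of 18 cases, with a median of 2.19 (adjusted p = 0.00013, and adjusted p = 0.0782 with an estimated correlation), and IGFBP3, PIK3R1 and PAPPA2 fell. Matrix proteases and their inhibitors rose in 14 of 20 cases, with a median of 1.02 (adjusted p = 0.00374, and adjusted p = 0.126 with an estimated correlation). MMP11 rose 222-fold to 367 ± 39.6 CPM and MMP10 120.4-fold to 331 ± 78.6 CPM, and TIMP3, ADAMTS4 and SERPINE1 fell. ADAMTS4, SERPINE1, IGFBP3 and PAPPA2 were named after their values were seen. Genes of the WNT pathway rose in 17 of 29 cases and fell in 6, with a median of 1.53 (adjusted p = 0.0178, and adjusted p = 0.102 with an estimated correlation). RSPO3 rose 115-fold to 8.52 ± 0.306 CPM and SFRP1 24.1-fold to 67.2 ± 3.73 CPM.

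Steroid and retinoid metabolism genes rose in 12 of 16 cases at day 8, with a median log2 fold change of 2.07 (adjusted p = 0.00427, and adjusted p = 0.0941 with an estimated correlation). ALDH1A1 was at least 146-fold higher and RBP1 rose 38.3-fold, while SRD5A1 and STS, named after their values were seen, fell. Cholesterol synthesis genes rose in 17 of 23 cases, with a median of 0.68 (adjusted p = 0.00252, and adjusted p = 0.249 with an estimated correlation). FDPS and STARD4, named after their values were seen, fell. Genes of the defence against oxidative stress rose in 16 of 26 cases and fell in 5, with a median of 0.64 (adjusted p = 0.0178, and adjusted p = 0.102 with an estimated correlation). TXNIP rose 11.9-fold. Angiogenic factors rose in 11 of 16 cases, with a median of 1.69 (adjusted p = 0.04, and adjusted p = 0.235 with an estimated correlation). That call was lost without undifferentiated replicate 3 (adjusted p = 0.053, against 0.0268 to 0.053 over the libraries left out). HGF rose 39.3-fold and VEGFA 13.6-fold to 201 ± 0.277 CPM, while VEGFC, EFNB2 and FGF2 fell, the last named after its value was seen.

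Interferon-stimulated genes, which passed the list test at day 3 with the preset but not with an estimated correlation (adjusted p = 0.443), did not pass at day 8. Of these, 8 members were higher, 6 lower and 14 not past the threshold at day 8 (median 0.08, adjusted p = 0.86). Glycolysis genes, whose day 3 call was also lost with an estimated correlation (adjusted p = 0.58), did not pass at day 8 either (median −0.23, adjusted p = 0.443). Of 27 interstitial matrix genes, 16 were lower, 10 higher and 1 not past the threshold (median −0.73, adjusted p = 0.22). COL11A1 fell 18.1-fold and DCN rose 31.1-fold. COL1A1 was at 6946 ± 1175 CPM (log2 fold change −0.79, SE 0.18, adjusted p = 0.00288), a call lost on the log2(TPM + 1) scale without a filter. Adjusted over the list alone, 2 more TGF-beta and BMP genes were higher and 1 more contractile gene lower, and the other 27 lists gave the same counts. The median and the mean differed in sign for epithelial (−0.01 and 0.22), endothelial (−0.11 and 0.59) and leukocyte markers (−0.52 and 0.04) and for interferon-stimulated genes (0.08 and −0.19). The list test followed the mean for the epithelial markers and the median for the others. The self-test found 74.6% of 2-fold and 92.4% of 4-fold changes at day 8, with 10 false calls. It again changed 200 genes, against 10508 called in the data, so its figures do not carry over.

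**Figure D3:**
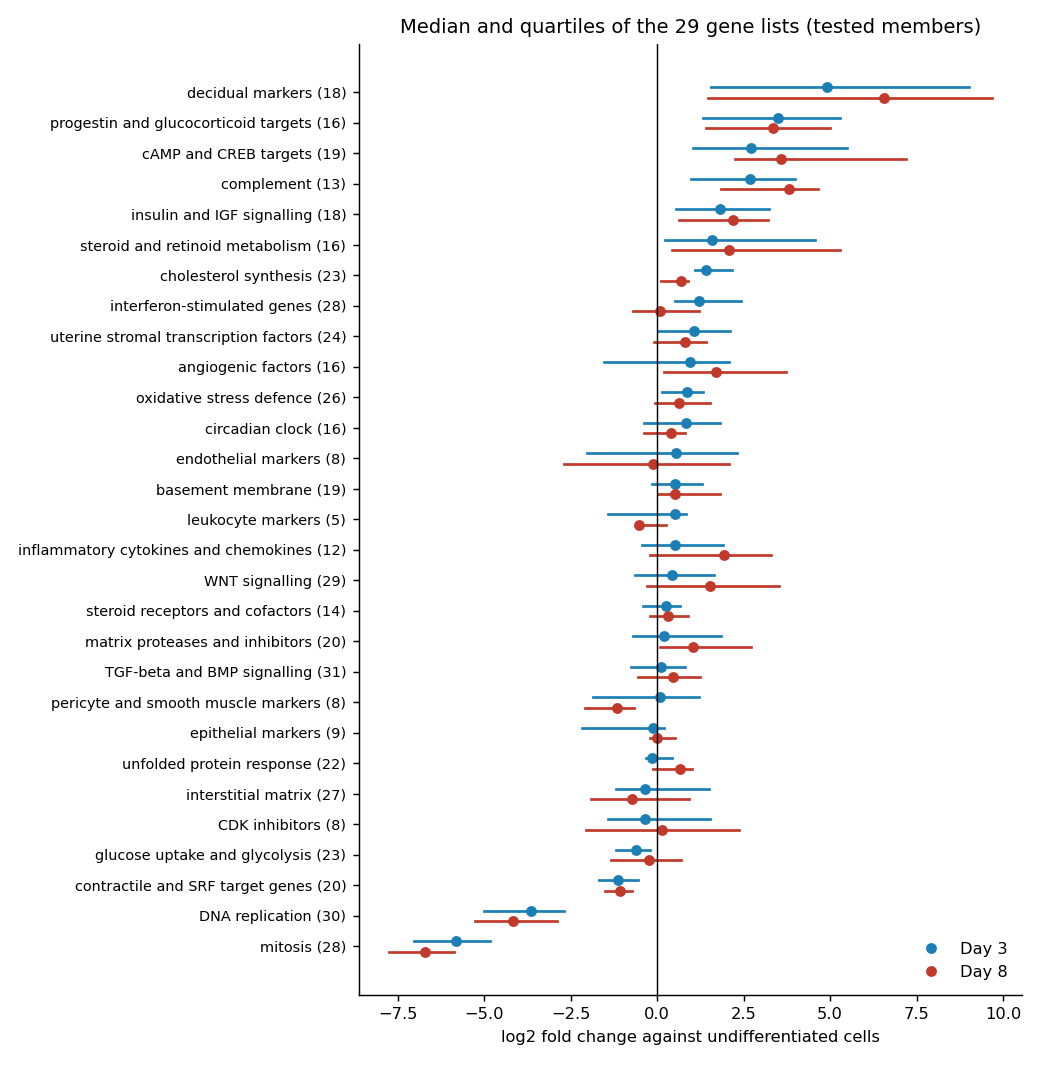
Median log2 fold change against undifferentiated cells, with quartiles, of 29 gene lists at day 3 (blue) and day 8 (red), and the number of tested members in brackets. Mitosis (−5.81 and −6.73) and DNA replication (−3.65 and −4.18) lie lowest and decidual markers (4.91 and 6.55) highest, and interferon-stimulated genes go from 1.20 to 0.08.

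The comparison of day 8 with day 3 asked whether the programme moves on between the time points, which bears on the multi-phasic process named in the title of the series. PRL rose 30.5-fold between them (log2 fold change 4.93, SE 0.14, adjusted p = 6.05e-08), whereas IGFBP1 was not past the threshold (log2 fold change 0.37, SE 0.14, adjusted p = 0.0518). BMP2 rose 17.5-fold (SE of log2 0.09, adjusted p = 2.09e-09). HAND2 fell by 1.54 (SE 0.09, adjusted p = 3.81e-07) and PGR by 1.11 (SE 0.11, adjusted p = 1.27e-05) on the log2 scale.

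Between day 3 and day 8, 6962 genes (46.0%) changed, 3496 higher and 3466 lower, and 2541 changed by at least 2-fold, 1265 higher and 1276 lower. Changes of 8-fold or more comprised 275 higher and 115 lower genes. A further 1081 genes had an unadjusted p under 0.05 and were not called. The count of changed genes was 4638 without day 8 replicate 1, where the remaining day 8 library was assumed to vary like the others. The 2-fold count was 1325 on the log2(TPM + 1) scale and 1313 without a filter. The share of changed genes that were higher was 50.2%, against 42.1% on the log2(TPM + 1) scale and 45.6% with upper-quartile scaling of the counts. The 8 largest rises included MMP10, 497-fold, PMEPA1, 265-fold to 23.2 ± 1.69 CPM, and C8orf4, 181-fold to 78.8 ± 9.56 CPM. CXCR4, a chemokine receptor gene, had 0.0206 ± 0.0188 CPM at day 3 and 14.1 ± 0.893 CPM at day 8, a ratio of 666 with a 95% interval of 184 to 5512. PDGFB had 0.0287 ± 0.0257 and 12.7 ± 0.637 CPM, a ratio of 402 with a 95% interval of 137 to 1951. The largest falls included CCDC85A, 85.1-fold, APOL1, 31.6-fold, and IFI44L, 24.3-fold to 0.895 ± 0.439 CPM.

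Between day 3 and day 8, 8 lists passed the list test, 3 upward and 5 downward, and none did with an estimated correlation. Targets of cAMP and CREB rose in 14 of 19 cases, with a median log2 fold change of 1.44 (adjusted p = 0.000618, and adjusted p = 0.12 with an estimated correlation), and NR4A3, PDE7B and PER1 fell. SIK1 rose 5.33-fold to 149 ± 2.52 CPM and RGS2 14.2-fold. Genes of the unfolded protein response rose in 16 of 22 cases, with a median of 0.72 (adjusted p = 5.11e-05, and adjusted p = 0.12 with an estimated correlation). ATF3 rose 4.07-fold, CHAC1 2.87-fold and DNAJB9 2.7-fold, and TRIB3 fell by 0.44 on the log2 scale. WNT pathway genes rose in 17 of 29 cases, with a median of 0.76 (adjusted p = 0.00362, and adjusted p = 0.12 with an estimated correlation). FZD8 rose 13.2-fold and SFRP1 18.1-fold, and WNT16, FZD1, FZD7, DKK1 and DKK3 fell. NR4A3, TRIB3, FZD1, FZD7 and DKK3 were named after their values were seen.

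Interferon-stimulated genes fell in 22 of 28 cases between day 3 and day 8, with a median log2 fold change of −1.31 (adjusted p = 1.16e-06, and adjusted p = 0.311 with an estimated correlation). IFIT1 fell 12-fold and IFIT2 9.68-fold, and IFITM1, named after its value was seen, rose by 0.73 on the log2 scale. Cholesterol synthesis genes fell in 21 of 23 cases and rose in none, with a median of −0.63 (adjusted p = 1.6e-07, and adjusted p = 0.192 with an estimated correlation). INSIG1 fell 3.52-fold and HMGCS1 2.94-fold, and PMVK and CYP51A1 were not past the threshold, PMVK being named after its value was seen. Mitosis genes fell further in 17 of 28 cases, with none higher and a median of −0.93 (adjusted p = 2.8e-07, and adjusted p = 0.311 with an estimated correlation). Pericyte and smooth muscle markers fell in 4 of 8 cases, with a median of −1.34 (adjusted p = 0.0276, and adjusted p = 0.192 with an estimated correlation). SYNM rose, a call lost under some alternatives, and 3 were not past the threshold. Of the pericyte markers, ABCC9 fell 4.85-fold and KCNJ8 4.33-fold. Circadian clock genes fell in 10 of 16 cases, with a median of −0.51 (adjusted p = 0.00791, and adjusted p = 0.151 with an estimated correlation). NFIL3 fell 2.98-fold and DBP 3.17-fold, and ARNTL and NR1D1, named after their values were seen, rose by 0.53 and 0.36 on the log2 scale.

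Targets of progestins and glucocorticoids were lower in 10, higher in 4 and not past the threshold in 2 of 16 cases (median −0.90, adjusted p = 0.126). TSC22D3 fell 4.42-fold and FKBP5 2.25-fold from day 3 to day 8. Of 24 transcription factors, 11 fell and 5 rose (median −0.16, adjusted p = 0.0751), with log2 fold changes of −1.01 for HOXA10 and −0.88 for HOXA11. ZBTB16, of the progestin list, fell by 1.99 on the log2 scale. Decidual markers rose in 9 and fell in 6 of 18 cases (median 0.39, adjusted p = 0.471), with FOXO1 1.33-fold and WNT4 2.61-fold higher. CEBPB was not past the threshold (log2 fold change 0.01, SE 0.13, adjusted p = 0.944). Adjusted over the list alone, 11 decidual, 6 progestin, 9 interstitial matrix, 6 epithelial, 2 leukocyte, 18 WNT, 7 insulin and IGF, 17 unfolded protein response, 10 oxidative stress and 9 glycolysis genes were higher. In the same way, 14 interstitial matrix, 6 protease, 9 TGF-beta and BMP, 12 oxidative stress and 6 glycolysis genes were lower, and the other counts were the same. The median and the mean differed in sign for progestin targets (−0.90 and 0.00), basement membrane (−0.18 and 0.10), contractile genes (−0.40 and 0.10), inflammatory genes (−0.36 and 0.68) and oxidative stress genes (−0.06 and 0.20), and the list test followed the median in each. The self-test found 74.6% of 2-fold and 90.9% of 4-fold changes in this comparison, with 15 false calls. Here too it changed 200 genes, against 6962 called in the data, so its figures do not carry over.

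The changes of both time points against undifferentiated cells were compared next. Of the genes higher at day 3, 3873 were also higher at day 8, where independent lists of these sizes would share 1890.5. Of the genes lower at day 3, 4215 were also lower at day 8, against 1910.2 for independent lists, which gave 8088 genes with a shared direction. A further 561 genes were called in opposite directions. Both comparisons used the same 3 undifferentiated libraries, which were too few to split. In 20 simulated data sets in which no group differed, a mean of 0.4 genes were called at day 3 and 0.15 at day 8, and none in a shared direction. With so few calls, these data sets cannot show how much overlap the shared libraries add to the calls made here. In 20 in which day 8 equalled day 3, a mean of 0.7 genes, and at most 4, were called between day 8 and day 3, and none met the definition of a transient change.

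By the calls in the 3 comparisons, 4645 genes (42.4% of the day 3 calls) were changed at both time points with no call between them, 2031 of them higher and 2614 lower. A further 2009 (18.3%) moved on in the same direction from day 3 to day 8, 1040 upward and 969 downward. Partial return at day 8 was seen in 1434 genes (13.1%). A further 1420 (13.0%) had a day 3 call, an opposite call between time points and no call against undifferentiated cells at day 8. A reversal was seen in 561 (5.12%), of which 263 were higher and 298 lower at day 3. A late change was found in 1347 genes, with 821 higher and 526 lower. These had no day 3 call and calls in 1 direction for both day 8 contrasts. Genes called at a single time point without a call between time points belong to none of these classes. The class sizes leaned on single libraries. Partial return was called for 713 genes without day 8 replicate 1 and 733 without replicate 2, and a continued change for 1324 without day 8 replicate 2. No call between time points is not proof of no change, and with fits to only the groups compared 3403 genes were held. Among held genes CGA was at 277 ± 40.2 and 278 ± 5.27 CPM at day 3 and day 8. KIAA1199, a hyaluronan-binding protein gene, went on rising, from 1.55 ± 0.272 through 162 ± 30.3 to 2153 ± 131 CPM. S1PR3, a sphingosine 1-phosphate receptor gene, was transient, with 64.8 ± 2.42, 1092 ± 42.5 and 63.1 ± 2.08 CPM in undifferentiated, day 3 and day 8 cells. LINC00473 partly returned, from 43.7 ± 4.24 to 15.5 ± 1.32 CPM. CXCR4 was late, with a ratio of 1594 to undifferentiated cells at day 8 and a 95% interval of 285 to 63030.

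**Figure D4:**
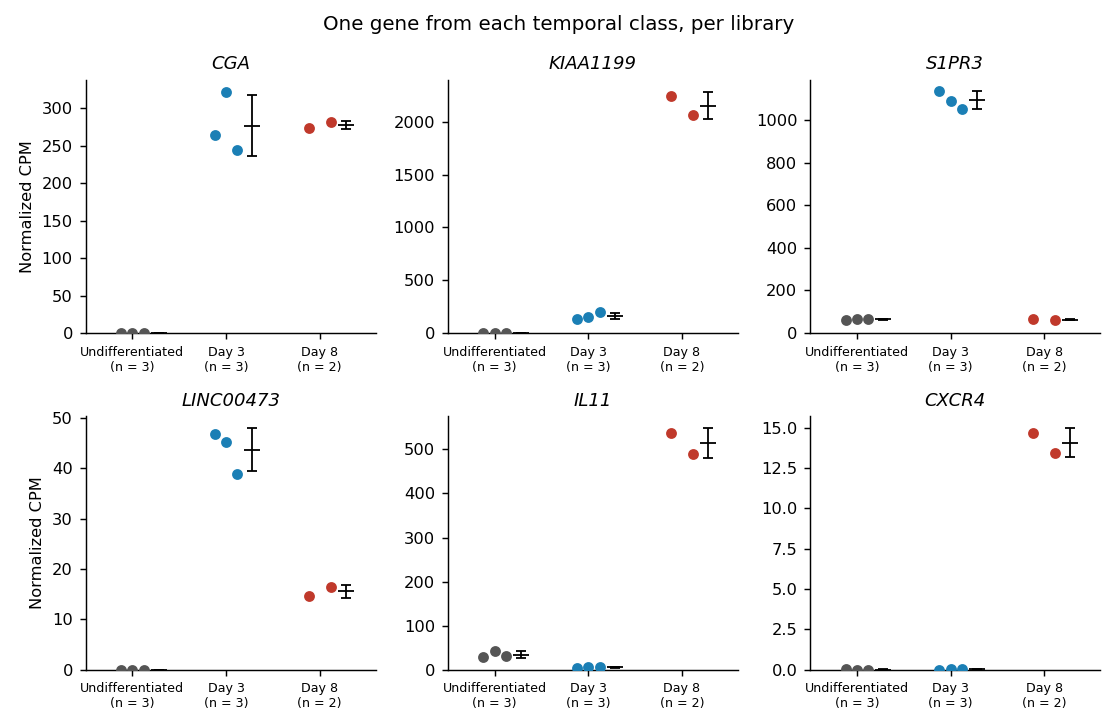
Normalized CPM per library of 1 example gene for each course: CGA (held), KIAA1199 (continued), S1PR3 (transient), LINC00473 (partly returned), IL11 (reversed) and CXCR4 (late). IL11 went from 34.3 ± 7.82 through 5.41 ± 1.10 to 514 ± 33.4 CPM, below and then above its undifferentiated level.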

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

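The 3 candidate gene lists tested in this part were chosen only after the pattern was seen, and their tests were run once. Of the 244 genes named by the rule, 25 were called in opposite directions against undifferentiated cells at day 3 and day 8, with the difference between the time points also called. Of these, 18 were lower at day 3 and higher at day 8, and 7 the reverse. Over all tested genes, 561 met the same definition, of which 298 were lower at day 3 and higher at day 8. Values are log2 fold changes at day 3 and at day 8 against undifferentiated cells, followed by the change from day 3 to day 8.

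Lower and then higher were MMP10 (−2.05, 6.91 and 8.96), PMEPA1 (−2.13, 5.92 and 8.05), ITGA11 (−0.45, 6.14 and 6.59) and IL11 (−2.65, 3.91 and 6.56). The same held for IL24 (−3.87, 1.48 and 5.35), ANGPTL4 (−1.57, 3.71 and 5.28), STC1 (−1.66, 3.14 and 4.80), INHBB (−3.22, 1.52 and 4.74) and PLAU (−1.24, 3.29 and 4.53). ANKRD1 followed this course (−3.49, 0.60 and 4.10), as did IGFBP5 (−1.22, 2.75 and 3.97), FZD8 (−2.06, 1.66 and 3.72), TGFB2 (−0.80, 2.67 and 3.47) and EDN1 (−1.52, 1.46 and 2.98). Smaller changes were those of VDR (−0.90, 1.36 and 2.26), SLC2A1 (−0.54, 1.66 and 2.21), PFKFB3 (−0.61, 1.58 and 2.19) and CTGF (−0.55, 1.46 and 2.01).

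Higher and then lower were CCDC85A (1.37, −5.04 and −6.41), APOL1 (2.38, −2.60 and −4.98), TIMP3 (0.68, −2.26 and −2.94) and PIK3R1 (1.45, −0.98 and −2.43). The other 3 were ABCC9 (0.82, −1.46 and −2.28), KCNJ8 (1.16, −0.96 and −2.11) and PER3 (0.72, −0.37 and −1.09). SGK1 and NFKBIA, chosen after their values were seen, also rose at day 3 and were lower at day 8.

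The call on 1 side was lost under some alternatives for 5 of the 25 genes. For ITGA11 the fall at day 3 was not past the threshold under 10 of its alternatives, and its libraries overlapped between the groups. ANKRD1 lost its day 8 call without a filter on low counts and without any of 4 single libraries, and PER3 its day 8 call without day 8 replicate 1 (adjusted p = 0.0965, against 0.00176 to 0.134 over its alternatives) and on all 3 TPM scales. PMEPA1 lost its day 3 call on log2(TPM + 1) with and without the filter, and CTGF on log2(TPM + 1) without it.

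For the 298 genes lower at day 3 and higher at day 8, an explanation was sought in 3 candidate lists, each expected to have at least 70% of its members higher at day 8 than at day 3 if it were the cause, and at most one in 3 if not. Handling stress at harvest of the day 8 libraries gave 46.7% (7 of 15 immediate-early and stress genes higher, 3 lower), low oxygen or spent medium gave 40% (6 of 15 higher, 3 lower), and TGF-beta or activin signalling gave 43.75% (7 of 16 higher, 6 lower). These shares count members higher at day 8 than at day 3, whatever their level in undifferentiated cells. Of the tested members, 1 of 15, 0 of 15 and 2 of 16, in that order, were among the 298 genes of the pattern. The lists held none of the 18 flagged genes with this course, SLC2A1, ANGPTL4, PMEPA1 and CTGF among them. This overlap therefore depends on how the lists were made, and no conclusion is drawn from it. Among all tested genes 23.1% were higher at day 8 than at day 3, so none of the shares decided. Handling, medium and signalling therefore cannot be told apart here as sources of the pattern, because each share lay between its bounds. A biological change between the time points, which the design names, may also underlie it and was not tested apart from these.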

How the results depend on the processing

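No test in this part was chosen after the result was seen: every alternative was planned. None of the results reversed under any alternative run. For the 16 summary counts, 246 alternatives gave a value within 1.5 times the main one and 16 did not. For the 38 lists called in a comparison, 419 alternatives kept the call and 37 lost it, and for 641 called results of named genes, 11831 kept it and 191 lost it. Alternatives in which a gene was filtered out are not in these counts. A change of the same sign without an adjusted p was counted as kept.

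On log2(TPM + 1) the 2-fold counts fell to 3300 at day 3, 3428 at day 8 and 1325 between them, and to 3294, 3415 and 1313 without a filter. The added 1 shrinks fold changes of low values by construction. The median of all genes moved by 0.18 at day 3, 0.13 at day 8 and −0.07 between them on log2(TPM + 1), by 0.21, 0.15 and −0.08 on log2(TPM + 0.1), and by 0.14, 0.10 and −0.06 on log2(TPM + 1) without a filter. It moved by 0.21 and 0.12 at day 3 and day 8 with library totals alone, and by at most 0.10 with the other scalings of the counts. On these TPM scales 61.3% and 61.4% of day 3 calls were higher, against 49.8% with the main choices.

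With an estimated correlation 1, 1 and 0 lists passed at day 3, at day 8 and between them, against 14, 16 and 8 with the preset one. Lists with an estimate below the preset 0.01 also lost the call, such as complement (−0.065) and oxidative stress genes (−0.021) at day 3. The list that kept its call at day 3 and day 8, targets of cAMP and CREB, had an estimate of −0.040. A lost call is therefore not by itself a sign of correlated members, nor a kept call a sign against them. The fry test, which does not compare a list with other genes, called 27, 25 and 24.

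Leaving out each library in turn gave 10114 to 11438 changed genes at day 3 (4954 to 5428 at least 2-fold), 8896 to 11090 at day 8 (4999 to 5326), and 4638 to 8973 between them (2204 to 2646). The lowest value between time points came without day 8 replicate 1 and the highest without undifferentiated replicate 3. Genes with a shared direction numbered 7054 to 8570. Courses over time held 3606 to 5087 (held), 1324 to 2841 (continued), 1153 to 1524 (transient), 713 to 2123 (partly returned), 377 to 764 (reversed) and 930 to 1448 (late) genes. The lowest count was without day 8 replicate 2 for continued genes, and without day 8 replicate 1 for partly returned genes, with 733 without replicate 2. A left-out day 8 library leaves 1, which is assumed to vary like the other groups, and fewer libraries lower the power to make calls. Lists called numbered 14 in each case at day 3, 16 to 17 at day 8 and 8 to 9 between them. The call of angiogenic factors at day 8 was lost without undifferentiated replicate 3. Undifferentiated libraries enter the contrast between time points only through the filter, the scaling and the shared spread. A fit to only the 2 groups compared gave 8699 changed genes between them, against 6962, and 3403 held genes, against 4645. The undifferentiated libraries thus lowered the count between time points in the main fit, by a route not tested further. The cause of the other changes was not tested.

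With the replicate number as a replicate block, 10600 genes changed at day 3 (5225 at least 2-fold), 9820 at day 8 (5155) and 6131 between them (2590), and 10533, 9742 and 5888 of these were called without it. The shared count was 7552 and the courses held 4729, 1638, 1407, 1185, 468 and 1227 genes in the order above, and 14, 17 and 8 lists passed. Libraries of the same number did not deviate alike from their groups: correlations over genes were 0.10, −0.17 and −0.12 for undifferentiated with day 3 replicates 1 to 3, −0.08 and 0.05 for undifferentiated with day 8, and 0.03 and −0.08 for day 3 with day 8. Genes are not independent replicates.

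Depth limits the genes near 0: a library's floor of 3 counts was 0.0745 to 0.111 CPM, so lower bounds and ratios of such genes are wide.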

Other observations

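The tests of time in culture, of leukocyte RNA and of a uniform interferon response were chosen only after the result was seen.

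All 58 mitosis and DNA replication genes were lower at day 3 and at day 8. A difference in depth would have ended these calls when every library was thinned to the smallest total, 25446911 counts, but 58 of 58 stayed lower at both time points. Scaling of the libraries was tested with library totals alone in place of TMM factors. This gave a median log2 fold change of −4.71 at day 3 (quartiles −6.05 and −3.37), where TMM gave −4.91. The factors ran from 0.912 to 1.08, so the exchange could move the median only slightly. The choice between these scalings thus does not account for the fall. Both are relative to library totals, so neither could show a change in total RNA per cell. Time or density in culture without the decidualizing medium could also lower these genes, and 0 undifferentiated libraries are labelled with a time in culture, so it cannot be told apart from the treatment. The decidualizing treatment, which the design names, stays open and was not tested apart from time in culture.

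Interferon-stimulated genes were mostly higher at day 3 and lower again at day 8, with 18 of the 22 rising members falling between the time points. Leukocytes would bring all their abundant transcripts, so RNA from leukocytes in the day 3 libraries was tested on the summed level of all 16 leukocyte markers listed. It was 7.84 ± 0.49 CPM in undifferentiated cells and 4.95 ± 0.41 CPM at day 3, while the interferon list went from 530 ± 25.5 to 850 ± 61.7 CPM. At day 3, 9 markers had no count and LYZ and LAPTM5 had under 0.1 CPM, PTPRC and CORO1A were called lower, and CD14, CD68 and FCER1G, called higher, rose by 1.45 CPM together. The calls of CD68 and FCER1G were lost under 9 and 4 alternatives. The summed and single levels argue against leukocyte RNA as the source. A single uniform interferon response at day 3 was also tested, and 5 members called lower at day 3, IFIT1, IFIT2 and IFIT3 among them, argue against it. Which signal raised some members and lowered others was not tested.

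The 3 undifferentiated and 3 day 3 libraries can be split into 3 against 3 in 10 ways, so the share of splits with a value as large as the real one cannot go under 0.1. The real split gave 10958 changed genes, 5208 at least 2-fold, and 14 lists, and it was in each case the 1 split that reached the value. Among the other splits the highest counts were 0 changed genes with edgeR, 0 at least 2-fold, and 13 lists. In those splits 24 to 550 genes had an unadjusted p under 0.05, and limma-voom also called 0. Each other split sets 2 libraries of one group and 1 of the other against the rest. It keeps part of the difference between the groups, so its list count is not a value without change. That difference also widens the spread within the mixed groups, which lowers the number of calls. The 0 changed genes are therefore not a value without change either. In simulated data with 1 list changed and genes drawn independently, 0 other lists passed with the preset correlation. With an estimated correlation 1 list passed at day 3.

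Lists that passed no list test, or passed it in other comparisons alone, gave these counts. At day 3, basement membrane genes were higher in 10 and lower in 5 of 19 cases (adjusted p = 0.126), and proteases and inhibitors in 10 and 7 of 20 (0.43). Markers of epithelial cells were higher in 2 and lower in 4 of 9 cases (0.573), of endothelial cells in 4 and 4 of 8 (0.971), of leukocytes in 3 and 2 of 5 (0.971), and of pericytes in 4 and 4 of 8 (0.971). WNT genes were higher in 13 and lower in 8 of 29 (0.386), TGF-beta and BMP genes in 14 and 14 of 31 (0.954), and inflammatory genes in 6 and 5 of 12 (0.499). Unfolded protein response genes were higher in 6 and lower in 10 of 22 (0.598), angiogenic factors in 8 and 6 of 16 (0.453), and clock genes in 10 and 5 of 16 (0.117).

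At day 8, steroid receptors and cofactors were higher in 7 and lower in 4 of 14 cases (adjusted p = 0.298), CDK inhibitors in 4 and 3 of 8 (0.86), and basement membrane genes in 12 and 4 of 19 (0.0636). Markers of epithelial cells were higher in 2 and lower in 1 of 9 (0.86), of endothelial cells in 3 and 3 of 8 (0.937), and of leukocytes in 1 and 2 of 5 (0.86). TGF-beta and BMP genes were higher in 16 and lower in 10 of 31 (0.136), inflammatory genes in 8 and 3 of 12 (0.146), unfolded protein response genes in 13 and 2 of 22 (0.0636), and clock genes in 9 and 5 of 16 (0.473).

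From day 3 to day 8, steroid receptors and cofactors rose in 5 and fell in 4 of 14 cases (adjusted p = 0.725), replication genes in 5 and 7 of 30 (0.145), CDK inhibitors in 3 and 3 of 8 (0.881), and interstitial matrix genes in 8 and 13 of 27 (0.145). Basement membrane genes rose in 6 and fell in 6 of 19 (0.967), proteases and inhibitors in 11 and 5 of 20 (0.125), and contractile genes in 6 and 11 of 20 (0.408). Markers of epithelial cells rose in 5 and fell in 1 of 9 (0.0747), of endothelial cells in 2 and 3 of 8 (0.983), and of leukocytes in 1 and 1 of 5 (0.79). Insulin and IGF genes rose in 6 and fell in 5 of 18 (0.726), TGF-beta and BMP genes in 15 and 8 of 31 (0.141), inflammatory genes in 4 and 6 of 12 (0.868), and complement genes in 5 and 3 of 13 (0.408). Steroid and retinoid genes rose in 8 and fell in 5 of 16 (0.408), oxidative stress genes in 9 and 10 of 26 (0.565), glycolysis genes in 8 and 5 of 23 (0.408), and angiogenic factors in 7 and 5 of 16 (0.408).

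Among markers of other cell types, KDR, which endothelial cells also make, rose from 0.0526 ± 0.0244 to 25.8 ± 6.01 CPM at day 8, while TIE1 and ESAM fell, so the endothelial markers moved apart. At day 3 the epithelial markers KRT18, KRT19, CLDN1 and PAX8 were called lower (KRT18 4.52-fold, KRT19 4.21-fold), and KRT7 and CLDN7 higher (3.90-fold and 2.32-fold). At day 8 KRT19 had 110 ± 7.52 CPM, against 114 ± 16.3 in undifferentiated cells. Within groups, the squared differences between libraries, over genes with at least 50 counts, came to chi-square values per gene of 11.2 for undifferentiated replicates 1 and 2, 61.7 for 1 and 3 and 68.0 for 2 and 3. They were 9.22, 17.3 and 15.7 at day 3 and 5.33 at day 8, so undifferentiated replicate 3 lay farther from the others of its group.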
